A study of Brassica rapa with 6 samples.

How the data were processed

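Total RNA from leaf and petiole of wild-type Chinese cabbage was extracted with Trizol, made into small RNA libraries with the Illumina TruSeq kit and sequenced on a HiSeq instrument, per the labels' protocols. The same protocols state that the ACGT101-miR program removed adapter dimers, junk and low-complexity reads, repeats, and reads of ribosomal, transfer, small nuclear and small nucleolar RNA. The aligner, genome build, miRBase release and the version of that program are not given in the sources used here. The table deposited by the authors gives a name, a mature sequence and, per the file headers, a normalized count for each of the 6 libraries. These signal values were normalized by the authors before they were deposited, per the file headers, and they are neither whole numbers nor ever negative. How the authors' scaling factor per library was set is not given in the sources used here, and the labels' protocols speak of more small RNA libraries than the 6 analysed here, so others may have entered the same normalization. Names follow the software's usual form, read here as follows. The species prefix and number are those of the matched miRNA, L and R mark bases added or removed at the ends, and ss marks substitutions. The labels p5 and p3 mark the sides of a precursor without an annotated mature form, and PC marks predicted miRNAs.

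The low values of each library lay on a regular step, taken as 1 read, with a size of 1.04, 1.04 and 1.06 in the leaf and 0.945, 0.959 and 0.904 in the petiole libraries. Of values under 60 reads, 68.9% to 75.5% were whole reads and 96.4% to 99.2% whole reads or whole reads plus 0.5, within 0.02 reads, so reads had been divided between entries and counts could not be taken back. Dividing by the step gave the reads behind the totals in the report. No library held a value of 1 read, at most 1 value of 2 reads was found per library, and 51 to 82 values lay at 5 reads, so a 0 is reported as listed at 0, with no fold against it and no limit from counting. The mean total after scaling was 1.81 times higher in leaf than in petiole, while the mean step was 1.12 times higher. Low values rest on few reads, and counting error is largest there. Every column of per-library values was used.

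Samples were grouped by the tissue in their labels, 3 leaf and 3 petiole. Nothing in the labels says that the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. Replicate pairs of 1 tissue differed by more than counting noise (chi-square per degree of freedom from 6.64 to 21.0), so each library was counted once. Of 1069 entries, 58 repeated a sequence, always with the same values, and the first was kept. The design allowed for counts or normalized values and was fixed before the data were examined, as were the lists, the named miRNAs' rule and most of the alternatives. Because the values were normalized, the branch for normalized values applied, and the count models foreseen for raw counts were not run.

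Values were tested as log2(value + 1) with limma 3.58.1 (R 4.3.3), with a mean-variance trend, on miRNAs with a mean of at least 5 over the 6 libraries. Differences are petiole minus leaf, on that log2 scale, where the added 1 understates the change of low miRNAs. Where a tissue is listed at 0, low reads may be missing from the table, and the change may instead be overstated. Benjamini-Hochberg adjusted p under 0.05 was called. The same test was run on sums by family, with the letters, arms and species dropped and miR157, miR165 and miR170 joined to miR156, miR166 and miR171; predicted miRNAs were left out there. For lists, camera with a preset correlation of 0.01 was run over the lists with at least 3 tested members, with an estimated correlation and fry as alternatives. For lists, medians include miRNAs listed at 0 in 1 tissue at their fitted value, since no bound could be set for them. Shares of the summed counts were compared by an exact two-sided permutation test. Arms were compared with limma on log2 of the ratio of 5p to 3p form, each with 1 added, taking the most abundant form per arm of entries with the same species and locus name.

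The text names the 12 miRNAs with the largest rise and the 12 with the largest fall among called miRNAs without overlap between tissues, the 6 most abundant miRNAs, and the 2 most abundant tested members of each list; other names were chosen after their values were seen. The lists covered phase change and leaf shape, meristem, polarity and organ boundary, auxin signalling, copper, phosphate, sulfate and nitrogen, small RNA machinery, phased siRNA triggers and disease resistance, MYB and secondary metabolism, phloem-mobile families and animal families. Related miRNAs differ by few bases, so values of single members of a family are uncertain where reads could be divided among them. No genome was used here, so positions and host genes are not given.

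On simulated data for the 601 miRNAs, with 100 changed at each fold, the test called 71.0% of differences of 2-fold and 94.0% of 4-fold, with 6 calls among 401 unchanged miRNAs. For the 80 families it called 93.3% and 100% at these sizes, with 2 calls among 50 unchanged families. In the simulated lists, noise was independent between miRNAs and every member of 1 list was lowered by 1 on the log2 scale. The changed list was called, and 1 other, which shares miRNAs with it. As values of related miRNAs may move together, this is no test of the preset correlation. Of the 62 arm pairs, 15 were given a shift of 2 on the log2 scale, and 86.7% of these were called. The unchanged pairs were set to a difference of exactly 0 and could not be called, so the arm simulation gives no rate of false calls.

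Alternatives were quantile normalization, equal library totals, no filter or a mean of at least 50, leaving out each library, the replicate number as a block, limma without trend or with a robust fit, a pseudocount of 0.1, 0.5 (arms) or 10, a log2 difference of at least 1, keeping every entry, leaving out predicted miRNAs, and for shares leaving out the most abundant miRNA or counting detected miRNAs. Chosen after seeing the data were counting miRNAs with identical values once, leaving out families that look like tRNA, a common factor on the petiole libraries with the fewest calls, median centring for the lists, and leaving out arm pairs listed at 0 in a tissue.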

Results

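Small RNA was sequenced from the leaf and the petiole of wild-type Chinese cabbage (Brassica rapa), a leafy vegetable whose petiole is the thick stalk that joins the leaf blade to the stem. The plants were grown in a greenhouse, and each tissue was represented by 3 libraries. The design compared the miRNA content of the 2 tissues. The table held normalized read counts for 1069 entries. After merging entries that shared a mature sequence and all of its values, 1011 sequences remained, of which 549 carried names of predicted miRNAs. Summed over these sequences, the normalized count was 789728 ± 15787 in leaf and 436475 ± 10506 in petiole (mean ± SD, n = 3 each). Low values lay on a regular step in each library, and with this step taken as 1 read the totals stood for between 729593 and 771262 reads in leaf and between 457195 and 474192 in petiole. A sequence listed at 0 in a library was not taken as absent, since values of under 3 reads were almost missing from the table. Replicates of 1 tissue correlated at 0.94 to 0.96 across miRNAs and libraries of different tissues at 0.71 to 0.74, on the log2 scale; miRNAs are not independent replicates. The median coefficient of variation among miRNAs with a mean count of at least 50 was 9.32% in leaf and 9.04% in petiole.

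The miRNA profiles of the 2 tissues differed widely. Of 601 miRNAs tested, 298 differed at an adjusted p under 0.05 with limma, 128 of them higher and 170 lower in petiole. The largest rises included forms of miR319, a family that targets TCP transcription factors of leaf growth. Among the largest falls was miR167, which targets auxin response factors. Of the 298 called miRNAs, 223 differed by at least 1 on the log2 scale, and in 297 the 3 petiole values lay wholly above or wholly below the 3 leaf values. Among all tested miRNAs 359, or 59.7%, were separated in this way, against 10% by chance.

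The miRNAs with names from known families accounted for 79 of the higher and 138 of the lower calls among 325 tested. Predicted miRNAs gave 49 higher and 32 lower calls among 276 tested. By length, 21 nt miRNAs were more often lower, with 51 higher and 102 lower of 211 tested. Among the 235 tested entries of 24 nt, 39 were higher and 10 were lower, and whether these entries are miRNAs was not tested. The scale of the libraries sets part of this balance. When every library was rescaled to the same total, 428 miRNAs were called, 321 higher (75.0%) and 107 lower, against 43.0% higher on the deposited scale. That rescaling moved the median log2 difference of all tested miRNAs from 0.18 to 0.97. It raises petiole values against leaf values, so a higher call could not turn lower. That all 128 higher calls stayed higher and called is therefore no check on them. Of the 170 lower calls, 14 were called higher instead. In all, 110 higher and 102 lower calls held their direction and stayed called under the deposited scale, equal totals and quantile normalization.

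**Figure D1:**
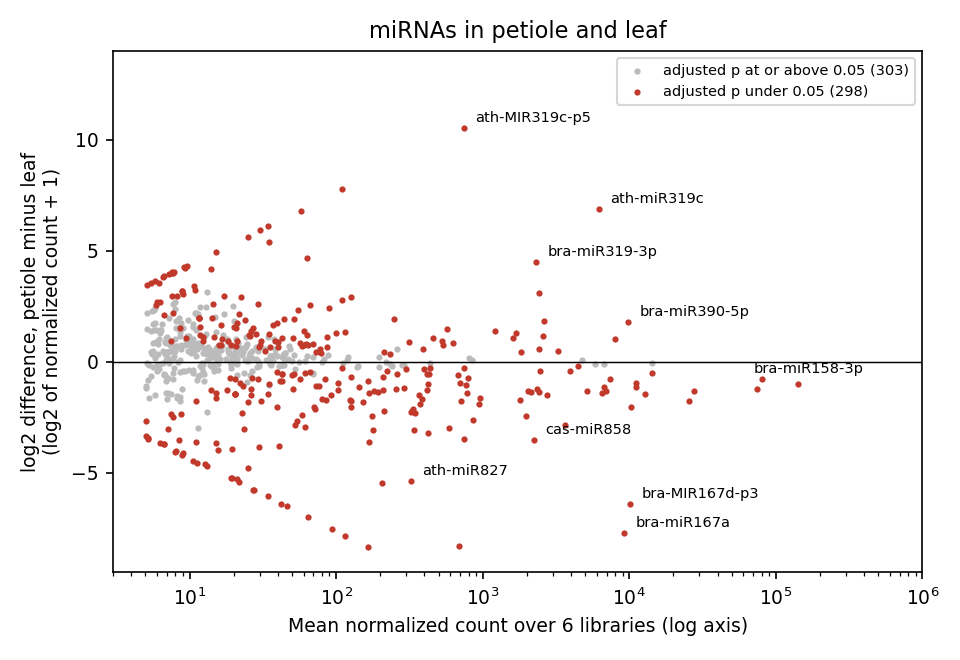
Each point is 1 of the 601 tested miRNAs, with its mean normalized count over 6 libraries on a log axis and its log2 difference (petiole minus leaf, after adding 1) on the vertical axis. Red points are the 298 miRNAs with an adjusted p under 0.05 in limma and grey points the others; the outer lines of points at low counts are miRNAs listed at 0 in all libraries of 1 tissue.

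Members of the miR319 family led the miRNAs higher in petiole. The form ath-miR319c_L+1R-1 (TTTGGACTGAAGGGAGCTCCT) rose from 104 ± 20.2 in leaf to 12264 ± 1094 in petiole (SD, n = 3), a 118-fold difference with a log2 change of 6.89 ± 0.14 (SE) and a limma adjusted p of 2.1e-07. The annotated bra-miR319-3p (TTGGACTGAAGGGAGCTCCCT) rose from 197 ± 43.3 to 4453 ± 624, a log2 change of 4.50 ± 0.17. The entry ath-MIR319c-p5 (ATCTGCCGACTCATCCATCCA) is named for the 5p side of the precursor. It was listed at 0 in all 3 leaf libraries and had 1356, 1639 and 1468 in the petiole libraries. Its sequence does not pair along its length with ath-miR319c_L+1R-1, so it was not taken as the star strand. The further miR319 forms, aly-miR319b-5p_L-1, ath-miR319a_R+1_1ss15GA and ath-miR319a_L+1R-1, were listed at 0 in leaf and averaged 115, 68.6 and 49.9 in petiole. The form mtr-miR319a-3p_R+1 went from 1.21 ± 2.10 to 68.9 ± 3.37. The other miRNAs among the 12 largest rises were bra-MIR9566-p5 and 4 predicted miRNAs. Of these, PC-5p-9832_350 (GGAGCACGTATTTCTATCAATT) was listed at 0 in leaf and reached 219 ± 8.90 in petiole, and PC-5p-20820_189 rose from 4.0 ± 1.47 to 123 ± 19.4. PC-3p-28364_146, PC-3p-43637_102 and bra-MIR9566-p5 were also listed at 0 in leaf, with petiole means of 60.1, 19.3 and 30.4.

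The miRNAs most reduced in petiole included abundant miR167 forms. The mature bra-miR167a (TGAAGCTGCCAGCATGATCTA) fell from 18299 ± 1028 in leaf to 86.5 ± 4.53 in petiole (SD, n = 3), a 211-fold difference with a log2 change of -7.71 ± 0.07 (SE) and a limma adjusted p of 5.8e-09. The star strand bra-MIR167d-p3 (GATCATGTTCGCAGTTTCACC) fell from 20141 ± 1476 to 235 ± 13.5, a log2 change of -6.41 ± 0.07. The less abundant forms, gma-miR167a_R+2 and ath-miR167c-5p, averaged 187 and 54.8 in leaf and were listed at 0 in petiole. The form gma-MIR5368-p3_1ss9CA fell from 1380 ± 97.7 to 5.56 ± 4.95, and its partner gma-MIR5368-p5_1ss1TC was 231 ± 35.6 in leaf and listed at 0 in petiole. Whether the entries named miR5368 and miR6173 are miRNAs or fragments of plastid ribosomal RNA was not tested, as no genome was used here. Both strands of bra-MIR5723 were listed at 0 in all petiole libraries, with leaf means of 331 ± 20.4 (p5) and 129 ± 11.1 (p3). The remaining members of the 12 largest falls, hbr-miR6173_L+1, bra-miR391-5p, bra-MIR5720-p5 and bra-miR9552b-3p, averaged 92.8, 84.7, 68.1 and 54.1 in leaf and were listed at 0 in petiole. Across the table, 27 called miRNAs were listed at 0 in every petiole library and 21 in every leaf library.

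The 6 most abundant miRNAs over both tissues were lower in petiole on the deposited scale. They made up 62.2% of the summed counts in leaf and 54.2% in petiole. The leading miRNA, bra-miR158-3p (TTTCCAAATGTAGACAAAGCA), averaged 188881 ± 6831 in leaf and 93463 ± 2442 in petiole (SD, n = 3), a log2 change of -1.01. Next came bra-miR159a, which targets GAMYB-type transcription factors, with 101347 ± 5631 and 59272 ± 1052, and bra-miR1885b, which targets disease resistance genes in Brassica, with 104775 ± 1905 and 44991 ± 1895. For bra-MIR5719-p3_1ss17AT the means were 39254 and 15718, for bra-miR171e 39614 and 11457, and for bra-miR172a 17006 and 11771; without leaf replicate 3 the log2 change of bra-miR172a was -0.50 and no longer passed. Of these 6, bra-miR171e kept a log2 change past the threshold under the deposited scale, equal totals and quantile normalization. With equal totals bra-miR172a was called higher instead (0.33), and the log2 difference of bra-miR159a turned to 0.08 and did not pass. After quantile normalization the difference was 0 for bra-miR158-3p and bra-MIR5719-p3_1ss17AT and not past the threshold for bra-miR1885b. Quantile normalization sets values by rank within a library, and bra-miR159a and bra-miR1885b only exchanged ranks (0.16 and -0.16). Ranks held alike in both tissues give 0 whatever the counts, so these values do not tell whether the counts differed.

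Summed by family, miR319, miR390 and miR824 were the most abundant families that rose in petiole, and the conserved families miR167, miR827 and miR858 fell, with log2 changes of -6.46, -5.40 and -3.52. Family sums were tested because reads can be divided among near-identical members. Of 80 families tested, 65 differed, 22 higher and 43 lower in petiole. All 22 higher families were also called higher with equal totals and after quantile normalization, and 29 of the 43 lower families were called lower in both. With equal totals a higher family could not turn lower, as that setting raises petiole values. With equal totals the split was 39 higher and 31 lower, with 4 families called in the reverse direction. After quantile normalization it was 34 higher and 32 lower, with 1 family called in the reverse direction. Equal totals moved the median family difference from -0.77 to 0.08.

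The miR319 family rose from 360 ± 48.7 to 18989 ± 1262 (SD, n = 3), and all 13 tested members were higher. Members listed at 0 in leaf, such as mes-miR319g_R+3 (11.5 in petiole), passed the filter on the mean through petiole alone. They could not come out lower. The miR390 family, which triggers the phased siRNAs that restrain auxin response factors, rose from 4911 ± 211 to 19521 ± 540, with 4 of 5 tested members higher. Its main form bra-miR390-5p (AAGCTCAGGAGGGATAGCGCC) rose from 4385 ± 183 to 15178 ± 345. The miR824 family, which targets a MADS-box gene of stomatal development, rose from 6806 ± 592 to 12862 ± 791. In the other direction, the miR167 family fell from 39247 ± 1752 to 444 ± 21.1, an 88.4-fold difference. Its 9 tested members comprised 8 lower and 1 higher, ptc-miR167f-3p_L-1, which was singled out after its values were seen and rose from 10.1 ± 3.68 to 37.9 ± 5.76. The miR858 family, which targets MYB factors of phenylpropanoid metabolism, fell from 4105 ± 380 to 356 ± 17.4, and the miR827 family from 647 ± 16.7 to 14.4 ± 2.09. On the deposited scale all 10 tested members of miR171 and all 7 of miR164 were lower, with family log2 changes of -1.81 and -1.07 that stayed negative and past the threshold under the deposited scale, equal totals and quantile normalization. Single members did not all hold: with equal totals aly-miR171b-5p was called higher (0.27) and bra-miR164a, the most abundant miR164 form, did not pass (-0.11, and 0.01 after quantile normalization). The families miR168, miR172 and miR394 did not pass the test on the deposited scale, with log2 differences of -0.06, -0.12 and 0.05, and with equal totals these became 0.80, 0.73 and 0.90 and did pass.

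**Figure D2:**
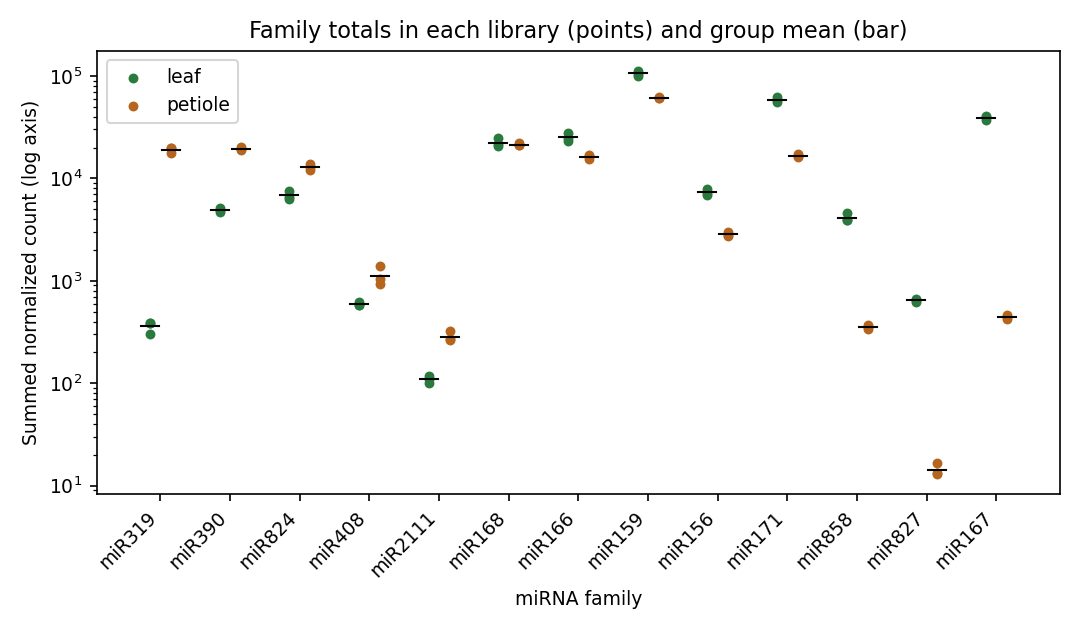
Summed normalized counts of 13 miRNA families on a log axis, with 1 point per library (leaf green, petiole brown, n = 3 each) and a bar at the group mean. The families miR319 and miR390 lie higher in petiole and miR167, miR827, miR858 and miR171 lower under the deposited scale, equal totals and quantile normalization, whereas the order of the tissues in miR166 turns with equal totals and in miR159 with equal totals and after quantile normalization.

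Lists of families grouped by the known roles of their targets were fixed before the data were examined. A list took every tested form of its families, whether or not that form is the strand that targets. The families of auxin signalling, of meristem, polarity and organ boundary, and of phased siRNA triggers and disease resistance were called lower in petiole relative to other miRNAs by camera with a preset correlation. None of the 3 calls held when the correlation was estimated (adjusted p = 0.563, 0.473 and 0.563 with an estimated correlation), and the other 7 of 10 lists did not pass. In the auxin list 20 of 32 tested members fell and 5 rose, with a median log2 change of -1.15 and an adjusted p of 0.0035 (adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, 22 fell and 6 rose. The falls came from miR167, miR160, which also targets auxin response factors, and miR393, which targets auxin receptors. The rises were miR390 forms and ptc-miR167f-3p_L-1. The form bra-miR160a-5p fell from 9290 ± 226 to 5424 ± 207 and ath-miR393a-5p from 3495 ± 819 to 1325 ± 292 (SD, n = 3). With equal totals neither form passed, with log2 differences of 0.08 and -0.54. The miR160 family sum turned to 0.10 with equal totals and was called higher.

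In the list of meristem, polarity and organ boundary, 28 of 45 tested members fell and 8 rose, with a median of -0.96 and an adjusted p of 0.0052 (adjusted p = 0.473 with an estimated correlation). The count adjusted over the list alone was the same, 28 and 8. The falls were led by miR171, which targets GRAS factors of the meristem, and miR164, which targets NAC factors of organ boundaries, and they included ath-miR166a-3p, which targets class III homeodomain-leucine zipper genes and went from 15367 ± 1359 to 6831 ± 296. After quantile normalization the log2 difference of ath-miR166a-3p was -0.32 and did not pass. The rises held 4 miR390 forms, 3 5p forms of miR166, and ath-miR396a-3p, the strand opposite the one that targets growth-regulating factors. With equal totals the sums of miR166 and miR396 turned to log2 differences of 0.21 and 0.47 and were called higher. In the list of phased siRNA triggers and disease resistance, 13 of 23 tested members fell and 1 rose, with a median of -0.59 and an adjusted p of 0.0035 (adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, 14 fell and 1 rose. Both miR1885 entries fell, bra-MIR1885b-p5 from 18750 ± 797 to 6874 ± 540, as did bra-miR400-5p, from 1480 ± 187 to 395 ± 62.0. The member that rose, ath-miR828_1ss14AG, was listed at 0 in leaf and averaged 15.8 in petiole. With equal totals the camera call remained for 1 of the 3 lists, that of auxin signalling, and with only miRNAs of a mean of at least 50 for none. After quantile normalization the list of meristem, polarity and organ boundary was not called (adjusted p = 0.344). A split of the 6 libraries that mixed the tissues gave 4 called lists.

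The list of phase change and leaf shape moved in both directions. Of its 47 tested members 19 rose and 20 fell (19 and 21 adjusted over the list alone), with an adjusted camera p of 0.716. All 13 tested miR319 members rose, those listed at 0 in leaf having passed the filter on the mean through petiole alone. Of 12 tested members of miR156, which marks the juvenile phase and represses SPL factors, 8 fell and 2 rose. The miR156 sum went from 7348 ± 484 to 2834 ± 124. The median of the list was -0.20, while its mean was 0.97 and camera gave an upward direction. Under fry the list was called higher (adjusted p = 0.00031), while camera with an estimated correlation did not call it (adjusted p = 0.790). The MYB list had 2 higher and 7 lower of 12 tested (2 and 8 adjusted over the list alone), led downward by cas-miR858 (TTTCGTTGTCTGTTCGACCTT), which fell from 4089 ± 381 to 355 ± 15.7. Its adjusted p was 0.273, with a downward direction in camera and a median of -0.51, while the mean was 0.04. The MYB list was called lower without the filter on the mean (adjusted p = 0.0454) and under fry (adjusted p = 0.0019), and with the filter the adjusted p with an estimated correlation was 0.790.

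Among nutrient-related lists, miRNAs of copper supply were mostly higher in petiole. Of 8 tested members 5 rose and 2 fell (5 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.552). The form cas-miR408_L-1R+1, which targets plantacyanin and laccases, rose from 301 ± 6.81 to 847 ± 179, and bra-miR398-5p_1ss8CT, from the family that targets copper/zinc superoxide dismutases, from 101 ± 1.09 to 393 ± 84.9 (SD, n = 3). The 3p forms of miR398 did not agree, since bol-miR398a-3p fell from 132 ± 7.50 to 39.4 ± 4.54 and bra-miR398-3p_R-1 rose from 21.3 ± 7.23 to 81.7 ± 23.7. In the phosphate list 2 of 7 rose and 2 fell, in both counts, with an adjusted p of 0.716. Its 2 most abundant members moved apart, since ath-miR827_2ss20CT21TA (TTAGATGACCATCAACAAATA) fell from 633 ± 15.7 to 14.4 ± 2.09 and bna-miR2111b-3p rose from 64.9 ± 4.46 to 166 ± 5.49. The median of that list was 0.70, the mean -0.19 and the direction upward in camera and downward in fry. The sulfate and nitrogen list had 7 higher and 4 lower of 13 tested (8 and 4 adjusted over the list alone; adjusted p = 0.637). In it, ath-MIR169e-p3 rose from 27.9 ± 6.66 to 152 ± 14.5 and cca-MIR395c-p5_1ss8CT fell from 205 ± 4.88 to 49.7 ± 9.47. Its median was 0.94 and its mean 0.38, while fry gave a downward direction.

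Among the miRNAs that target the small RNA machinery itself, the main forms of miR162 and miR403 fell while the abundant miR168 forms did not pass on the deposited scale. In that list 2 of 15 tested members rose and 4 fell, in both counts (adjusted p = 0.716), and the abundant bra-miR168b-5p_1ss21CA, which targets an Argonaute gene, had 14469 ± 1028 in leaf and 14018 ± 372 in petiole (SD, n = 3). Likewise bra-miR168a-3p had 6076 ± 1067 and 5514 ± 534. On equal totals both passed as higher, by 0.81 and 0.73 on the log2 scale. The form bra-miR162-3p, which targets a Dicer-like gene, fell from 3320 ± 451 to 1406 ± 47.6, and bra-miR403-3p, which targets another Argonaute gene, from 543 ± 5.52 to 190 ± 15.9. Families found in phloem sap, used as a marker list for vascular tissue, had 8 higher and 5 lower of 17 tested (8 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.706). Their median was 0.70 and their mean 0.12, with an upward direction in camera and a downward one in fry. No entry carried a name from the list of animal families.

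Shares of the summed counts shifted by small amounts between the tissues. The 21 nt class held 73.4% ± 0.64 in leaf and 77.0% ± 0.22 in petiole (SD, n = 3), the 22 nt class 17.4% ± 0.57 and 13.3% ± 0.21, and the 24 nt class 1.66% ± 0.04 and 2.92% ± 0.10. All other lengths together held 7.56% ± 0.07 and 6.79% ± 0.22. By first base, T, which is read as U in RNA and favours loading into the main miRNA Argonaute, made up 77.5% ± 0.38 in leaf and 73.2% ± 0.28 in petiole. The shares of A were 11.6% ± 0.28 and 14.9% ± 0.26, those of G 5.40% ± 0.19 and 6.33% ± 0.11, and those of C 5.55% ± 0.14 and 5.62% ± 0.21. Predicted miRNAs held 2.88% ± 0.07 and 3.11% ± 0.15. The exact two-sided permutation test gave p = 0.7 for C and p = 0.1 for the other classes, which is the smallest p that 3 against 3 libraries allow, so none could pass 0.05. Adjusted over the shares, these became 0.7 and 0.111 in the exact test. The summed 24 nt counts were 13128 ± 205 in leaf and 12751 ± 186 in petiole on the deposited scale. With every deposited entry kept, the petiole minus leaf difference turned to -3.27 percentage points for G and to 0.029 for other lengths. In that setting bra-MIR167d-p3, which starts with G (20141 in leaf, 235 in petiole), was counted again as bra-MIR167b-p3 and ath-miR167a-3p. As a share of the miRNAs detected, 21 nt turned to -4.55 and other lengths to 2.01.

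The 2 arms of a precursor did not always move together. Of 57 precursors with counts in both tissues, 28 changed their ratio of 5p to 3p form at an adjusted limma p under 0.05, 13 toward the 5p arm and 15 toward the 3p arm in petiole. The test as first fixed took 62 precursors and called 35, but in 5 of these both arms were listed at 0 in a tissue, where the added 1 alone sets the ratio. Leaving out every pair with an arm listed at 0 throughout a tissue, which removes 6 more, gave 27 calls among 51. Where both arms have counts, the ratio does not depend on the scale of a library, apart from the added 1. For bra-miR390 the log2 ratio went from 3.09 ± 0.03 in leaf to 1.82 ± 0.04 in petiole (SD, n = 3), as the 3p form rose from 514 to 4308. For bra-miR158 it went from -4.88 ± 0.17 to -6.73 ± 0.26, with the 5p form at 6434 in leaf and 892 in petiole. For bra-miR396 it went from 0.93 ± 0.04 to 0.01 ± 0.04, for bra-miR162 from -6.62 ± 0.46 to -4.02 ± 0.18, and for cas-miR408 from -0.24 ± 0.24 to -2.14 ± 0.17. The arm with more counts changed in 2 called pairs, bna-miR167d, from 2.31 ± 0.16 to -0.73 ± 0.24, and bra-miR395a, from -0.70 ± 0.06 to 0.99 ± 0.36. The 5p sequence of bna-miR167d is also that of ath-miR167a, whose ratio moved the other way, from -6.02 ± 0.17 to -3.21 ± 0.15, and the abundant bra-miR167a is in neither pair. Some sequences entered more than 1 pair, such as the shared 3p form of miR166a, so the pairs are not independent. These precursors were singled out after their values were seen. Arms were matched by name and their sequences were not required to pair, so an entry such as ath-MIR319c-p5 need not be the star strand.

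**Figure D3:**
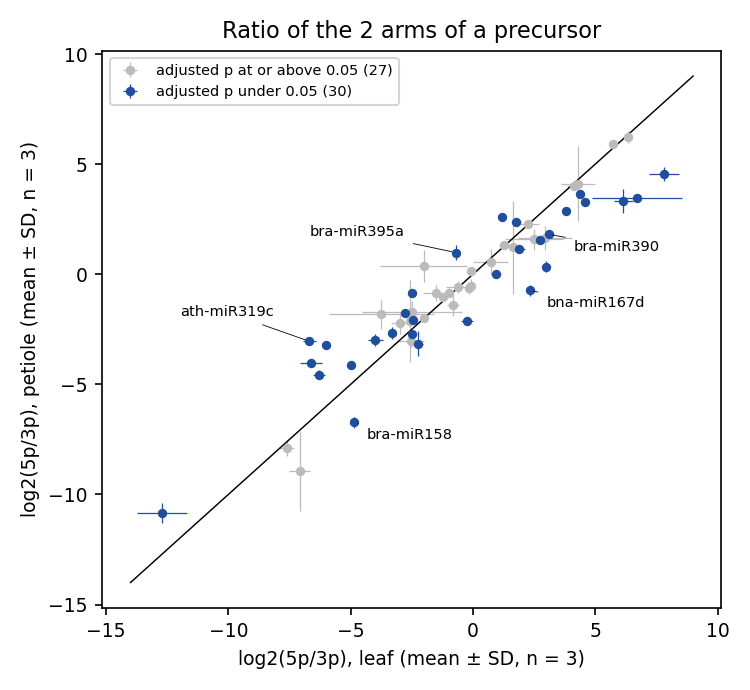
Mean log2 ratio of 5p to 3p form in leaf (horizontal) and petiole (vertical) for the precursors with counts in both tissues, with SD bars (n = 3) and the line of equal ratios. Blue points passed an adjusted p of 0.05 in limma over all 62 precursors, and in 6 of the points, ath-miR319c among them, an arm listed at 0 throughout a tissue leaves the ratio there to the added 1; of the blue points, bna-miR167d and bra-miR395a lie on opposite sides of 0 in the 2 tissues.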

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

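Counting identical values once, leaving out tRNA-like families, the common factor, median centring and leaving out arm pairs at 0 were tests chosen only after the results were seen. Of 42 named miRNAs, 34 kept direction and side of the threshold under every alternative run and 4 reversed under at least 1. The 298 calls ranged from 245 to 284 when 1 library was left out (245 without petiole replicate 1 or 3), and those of families from 61 to 65 and of arms from 27 to 32. With equal totals 321 miRNAs were higher and 107 lower, 235 calls being shared in direction with the deposited scale and 14 reversed; 39 families were higher and 1 list was called. Quantile normalization gave 284 calls (139 higher, 145 lower), 4 of them reversed, and 34 higher families, with 1 family, miR159, reversed. There miR159 and miR1885 exchanged ranks, with log2 differences of 0.23 and -0.23, which follows from rank alone. Only 186 miRNAs had a mean of at least 50, which gave 156 calls (50 higher, 106 lower) and 0 lists. A log2 difference of at least 1 left 10 higher families. For lists, the estimated correlation gave 0 and fry 7, which asks another question.

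Log2 differences that reversed were, after quantile normalization, 0.16 for bra-miR159a, 0.17 for bra-miR172a, 0.63 for bra-miR168b-5p_1ss21CA and 0.54 for bra-miR168a-3p, and with equal totals 0.083, 0.33, 0.81 and 0.73. For the miR168 forms, leaving out 1 library gave -0.0979 to 0.00477 (bra-miR168b-5p_1ss21CA) and -0.235 to 0.0061 (bra-miR168a-3p), above 0 only without leaf replicate 1. Without leaf replicate 3, bra-miR172a was at -0.50 and missed the threshold. The small RNA machinery list reversed with p of 0.829 (quantile), 0.888 (equal totals) and 0.723 (mean of at least 50), phosphate with 0.888 (equal totals) and 0.0015 (fry), and under fry also sulfate and nitrogen, 0.180, and phloem-mobile, 0.0079, all adjusted limma p. Over detected miRNAs, in place of counts, the petiole minus leaf share was -4.55 percentage points for 21 nt, 2.01 for other lengths and -1.01 for C. With every entry kept it was 0.029 for other lengths and -3.27 for G, where bra-MIR167d-p3 was counted again under its other names. Leaving out the most abundant miRNA gave -0.14 for C, and leaving out 1 library between -0.0244 (without petiole replicate 1) and 0.18, also below 0 without leaf replicate 2 (-0.0084). Beyond the settings' own construction, the cause was not tested.

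Leaf and petiole libraries share replicate numbers, but deviations of same-numbered libraries correlated at 0.02, 0.14 and -0.12, so the numbers were not taken to pair them, and not every library correlated best with its own number. The replicate block gave 280 miRNAs, 64 families, 3 lists and 31 arm pairs. With 10 splits of the 6 libraries no share under 0.05 is possible; the real and highest other counts were 298 and 0 miRNAs, 65 and 0 families, 3 and 4 lists, and 35 and 0 arm pairs, so that 1, 1, 3 and 1 splits gave as many.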

Other observations

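The families in this paragraph were picked after their values were seen. The miR158 family held 24.8% of the summed counts in leaf and 21.7% in petiole, miR1885 15.6% and 11.9%, and miR5719 6.23% and 4.51%. On the deposited scale miR1140, miR5654 and miR5721 were lower in petiole, with log2 changes of -1.50, -1.35 and -1.57, and these stayed lower with equal totals (-0.64, -0.50 and -0.72) and after quantile normalization (-0.76, -0.99 and -0.93). In miR5721 this is the larger member, as bra-MIR5721-p3 rose from 67.6 ± 6.29 to 89.7 ± 7.27. Higher in petiole were miR5726, from 2279 ± 101 to 5301 ± 181 (SD, n = 3), and miR5718, from 2338 ± 105 to 3561 ± 81.1, each with both tested members called. The miR391 family fell from 489 ± 60.3 to 8.39 ± 3.23. Its relative miR390 rose.

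Predicted miRNAs also separated the tissues. The most abundant of the called ones, PC-3p-66_19003 (TGGTTTGGATCTTGGAAGTCGT), fell from 9444 ± 413 to 3523 ± 85.0 (SD, n = 3). PC-3p-1067_1995 (TGTTCATCACTTCATTTCCCA) fell from 1377 ± 3.01 to 121 ± 1.56 and PC-3p-759_2494 (TCACTTCATTTCCCACTCCATT) from 766 ± 6.95 to 82.5 ± 8.20. Their sequences overlap, the end of the first being the start of the second, so their falls need not be independent. In the other direction the 24 nt PC-5p-1834_1331 (ATCCCGGGAAGATCAGACGTTGAT) rose from 454 ± 6.67 to 802 ± 66.7 and PC-3p-7117_460 (TCAACGTCTGATCTTCCCGGGATG) from 220 ± 19.3 to 408 ± 28.4. Apart from an end base of each, this last pair are exact reverse complements, so their rises need not be independent. Whether they are miRNAs was not tested. Of 213 miRNAs with a mean of at least 50 in a tissue, 14 were listed at 0 in all 3 libraries of the other.

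The tests of scale and of sequence overlap below were chosen only after the results were seen. Leaf libraries kept 1.81 times the summed count of petiole libraries after the authors' scaling, and more miRNAs were called lower than higher in petiole. The scaling alone is not a sufficient account of the calls, since the fewest calls under any common factor from a log2 of -3 to 3 on the petiole libraries was 279. Whether it sets the direction of the smaller changes stays open: 60% of the 170 lower calls were called lower both with equal totals and after quantile normalization, and no value in the table tells which scale is right. A lower miRNA content of petiole RNA, a biological difference that the tissues could have, and a scaling that leaves libraries on unequal totals cannot be told apart for the rest.

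A second pattern concerned entries named miR6300 and miR8175. Of their 30 sequences 21, or 70.0%, joined by exact overlaps of at least 12 nt into 1 stretch of 36 nt, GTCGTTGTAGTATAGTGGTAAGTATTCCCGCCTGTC, against 4 of 8 in 29 nt for miR162 and 5 of 19 in 27 nt for miR166. The longest stretch elsewhere, 42 nt in miR9563, held 6 of 48. Of 11 miR8175 sequences, 5 ended in GGCAACGGCGCCA, with the CCA end typical of mature tRNA. A candidate explanation is that these entries are fragments of 1 longer RNA, possibly a tRNA left after the removal of tRNA reads that the labels describe; no tRNA reference was used here, and tissue as a biological cause of their differences was not tested. Their values went both ways, with 10 of 24 tested called higher and 5 lower in petiole, but the 24 hold only 16 distinct sets of values and the 5 only 2. Leaving out miR6300, miR8175 and miR6478, of which 56.2% of sequences joined into 25 nt, gave 281 calls.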
